A study of Homo sapiens with 6 samples.

How the data were processed

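Gene-level RNA-seq values of 6 libraries of alisertib-treated A549 cells were compared, 3 without further drug and 3 after salinomycin. The genome build was GRCh38, per the submitters' processing notes, and the aligner, read counter and gene annotation were not given in the sources used here. The deposited signal values, 1 column per library, were whole numbers that the authors had rescaled, since their totals lay within 0.692% of each other. The lowest deposited signal was 1 in place of 0, so that 1 appeared to have been added to each value. Per the file headers, the same table held the authors' log10 means and their log2 fold changes, which lay within 0.005 of the log2 ratio of the deposited group means. It also held the authors' linear fold change, a ratio of salinomycin to untreated values per the file headers, a test score per gene and the p-values of the authors' comparison, with 1563 genes lacking an adjusted p. A second deposited table gave an enrichment score, a normalised enrichment score and p-values for each gene set, per the file headers, and neither the tool nor the release of the gene sets was given in the sources used here.

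Rescaling leaves steps in the low whole numbers of a library, from which its scale factor was estimated by likelihood. The factors lay between 0.831 (salinomycin replicate 1) and 1.2035 (untreated replicate 3). In libraries with a factor above 1, between 98.35% and 99.75% of low values could be reached from a whole number of reads. With a factor of 1 or less every value can be reached by construction, so 100% there is no check. Recovered reads ranged from 13539959 to 16293117 in untreated and from 14929443 to 19641149 in salinomycin libraries (n = 3 each; exact permutation p = 0.3, two-sided). These reads were used for counts of reads, for floors of 3 reads over a group, for 95% counting intervals of ratios and for a limma-voom fit, and they are estimates. Ratios of reads, their intervals and the bounds from floors were scaled for the recovered depth and library factors of each group. They therefore differ from the plain ratio of the printed reads. Intervals and floors cover counting error only. Pairs of libraries within a group differed by a chi-square per gene of 2.8 to 6.63 and none was treated as a repeat of another.

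The added 1 was subtracted, and values were divided by trimmed-mean (TMM) factors computed with 30% trimming of log ratios and 5% of levels. The factors were 0.925 to 0.9399 for untreated and 1.0653 to 1.0802 for salinomycin libraries. The resulting normalised units were tested as log2 of the value plus 1 with limma 3.58.1 in R 4.3.3, using a mean-variance trend and Benjamini-Hochberg adjustment. Tested genes had a value of 10 or more in at least 3 libraries, which left 13088 genes and set 3582 aside. Fold changes are on this log2 scale. The plan made before the data were examined assumed raw counts and a count model, and limma was used in its place because the values are rescaled and rounded. Differences in composition between libraries were tested by two-sided exact permutation, which with 3 against 3 cannot give a p below 0.1.

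The 32 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists. The pairs of lists that share a gene share ME1, MYC, SERPINH1 or SLC7A11. Named genes were the 10 largest rises and the 10 largest falls among genes past the threshold, with a mean of 5 or more CPM and no overlap between groups. They also included the 3 members of each list with the largest change past the threshold, the most abundant member of each list of other cell types, and 11 genes named in advance. The latter were CDKN1A, LMNB1, MKI67, GLB1, IL6, CXCL8, GDF15, TNFRSF10B, DDIT3, HMGCS1 and AURKA. The rule gave 120 genes, and other genes in the text were chosen after their values were seen. Some genes that the rule or this choice would name are not reported here. Coordinates are those of GENCODE release 29 on GRCh38, 1-based, to which 99.9% of symbols matched (16308 directly, 353 through another symbol and 9 not).

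The alternatives were limma-voom on recovered reads, median-of-ratios, upper-quartile and library-size scaling, no filter and a stricter filter, the replicate number as a block, and leaving out each library in turn. Pseudocounts of 0.5 and 8, median-of-ratios scaling for gene lists, and leaving out the mitochondrially encoded genes before scaling were added after seeing the data. The fit was tested on simulated data for this comparison with 200 genes drawn to change before the filter on low values, which left 13008 genes tested. It recovered 52% of 1.2-fold, 89.8% of 1.5-fold and 100% of 2-fold and 4-fold changes, and 11 of 181 calls (6.08%) were false. In the same simulation 0 of 30 unchanged lists were called. The data differ from it, with 5451 genes called higher and 5266 lower, so these shares need not carry over. Genes were simulated independently, so the lists there do not test correlation between members. The scale factors of 5 simulated libraries were estimated with an error of at most 0.0003. Reads of close paralogs, such as the aldo-keto reductase and metallothionein genes, and of genes with many pseudogenes, such as those of ribosomal proteins and keratins, could have been split by the counting, so their values are uncertain. ALDOA of the glycolysis list (137 and 390 units), CYP51A1 of the cholesterol list (27.8 and 108 units) and SRXN1 of the NRF2 list (6 reads in each group, not tested) had low values. Whether counting of overlapping genes lowered them was not settled. Strand use in counting was not given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3).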

Results

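RNA was sequenced from A549, an established human cell line derived from a non-small cell lung cancer. All the cells had been kept for 1 week in alisertib, an inhibitor of the mitotic kinase Aurora A, to make them senescent, a state of lasting arrest of cell division. A total of 6 libraries formed 2 groups of 3, which the labels describe as biological replicates. The untreated group received no further drug, and the salinomycin group received 2.5 µM salinomycin for 48 h before harvest. Salinomycin is a polyether ionophore, a compound that carries alkali metal ions such as potassium across membranes. The comparison asks how salinomycin alters the transcripts of senescent A549 cells, and no libraries of cells without alisertib were analysed here. Values were given for 16670 genes, and the rescaled totals lay between 16253579 and 16366234 per library. Reads recovered from the rounding steps of those values ranged from 13539959 (untreated replicate 3) to 19641149 (salinomycin replicate 1). Genes with a value above 0 numbered 15075 ± 88.9 in untreated and 15174 ± 137 in salinomycin libraries (SD, n = 3 each; exact permutation p = 0.4, two-sided).

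With salinomycin 18 of 20 endoplasmic reticulum (ER) stress genes, 19 of 24 genes of the ATF4 stress response and 23 of 25 cholesterol genes rose. All 13 mitochondrially encoded genes, all 19 tested members of a list of NRF2 targets and 8 of 10 WNT targets fell. These lists passed limma's camera test at a preset correlation, and none did with an estimated one (in that order, adjusted p = 0.29, 0.2, 0.052, 0.41, 0.052 and 0.17 with an estimated correlation). HSPA5, which encodes the main ER chaperone BiP, went from 10342 ± 491 to 120610 ± 2773 normalised units (SD, n = 3 per group), an 11.7-fold rise. MT-CO1, which encodes subunit 1 of cytochrome c oxidase, went from 187140 ± 10410 to 6413 ± 498 units, a 29.2-fold fall. Of 13088 genes tested with limma at a Benjamini-Hochberg adjusted p under 0.05, 5451 (41.6%) rose, 5266 (40.2%) fell and 2371 did not pass. At least 2-fold changes were found in 2197 genes that rose and 2418 that fell, a balance that turned over to 2837 and 2030 with scaling by library size alone. The 3 libraries of one group did not overlap those of the other for 10978 genes (83.9%), where chance gives 10%. The first principal component separated the groups and held 95% of the variance. Correlation across genes, which are not independent replicates, was 0.9929 to 0.9952 within groups and 0.8429 to 0.8476 between them (Pearson's r of log2 values). Scaling by library size alone moved the median log2 change of all tested genes by 0.19, from 0.022 to 0.212, and gave 6461 higher and 4353 lower genes. Each scaling sets where no change lies, and so the balance of higher and lower genes. Rises and falls are therefore relative to the other genes of a library and do not measure amounts per cell, which matters most for small changes.

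**Figure D1:**
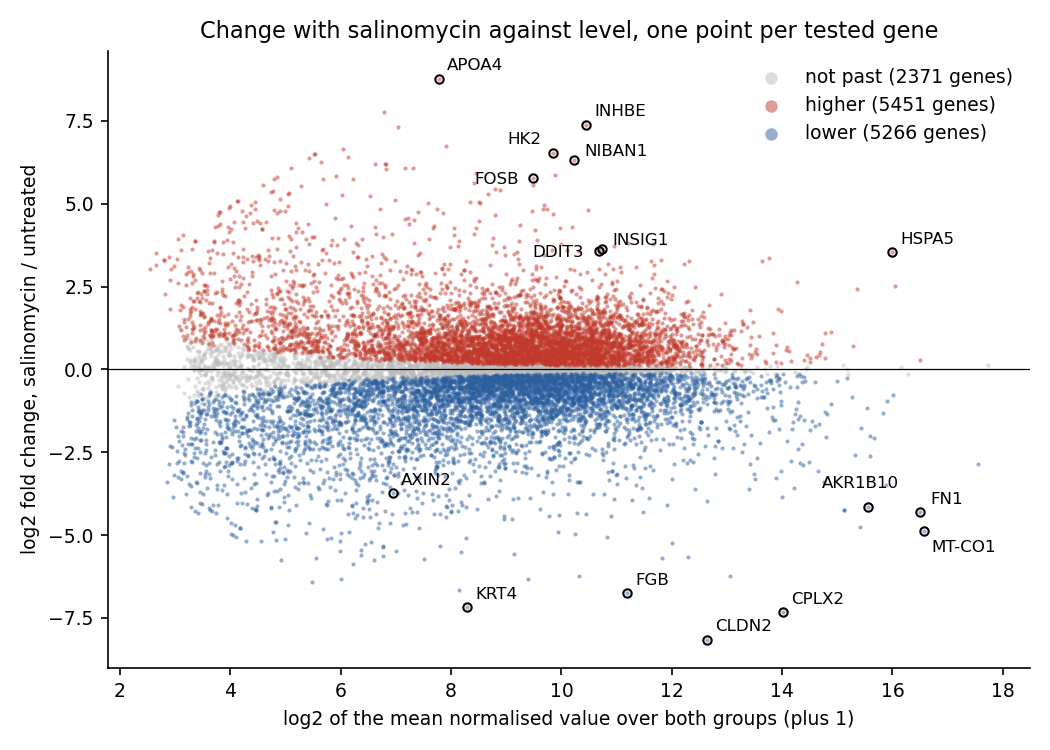
Each point is a tested gene, with the log2 of its mean normalised value (plus 1) over both groups on the horizontal axis and its log2 fold change, salinomycin over untreated, on the vertical axis. Red points are the 5451 genes that rose, blue points the 5266 that fell and grey points the 2371 that did not pass, and circles mark genes named in the text, among them HSPA5 at 3.54 and CLDN2 at -8.16.

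The 10 largest rises included genes with few or no untreated reads. APOA4, an apolipoprotein gene (chromosome 11, 116820700 to 116823306, GRCh38), had 0 reads in the untreated libraries and 437 ± 19.6 units with salinomycin (n = 3), at least 380-fold higher against a floor of 3 reads over the group. MUC4, which encodes a membrane mucin, was likewise at 0 reads in the untreated libraries and at least 188-fold higher with salinomycin. PIK3R5, a regulatory subunit gene of phosphoinositide 3-kinase gamma, had 2 reads over the untreated libraries and 910 over the salinomycin libraries. Scaled for depth and library factors, the ratio was 341 (95% counting interval 94.1 to 2820). INHBE, which encodes the inhibin beta E subunit (chromosome 12, 57452323 to 57459280), rose 167-fold, from 16.1 ± 4.73 to 2778 ± 141 units (log2 change 7.39, SE 0.175; limma adjusted p = 6.95e-12). HK2, a hexokinase gene (chromosome 2, 74833981 to 74893359), rose 93-fold, from 19.3 ± 5.72 to 1829 ± 28.9 units. DUSP9, a dual-specificity phosphatase gene, rose 106-fold (41.6-fold with a pseudocount of 8) and NIBAN1, a stress-inducible gene, rose 79.5-fold. The other 3 of the 10 largest rises, SHANK1, ESR2 and IRAK3, were between 73 and 73.9-fold, each from 5 or 6 untreated reads, and 20.7, 22.6 and 22.5-fold with a pseudocount of 8.

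The 10 largest falls included genes with high untreated levels. CLDN2, a gene of the tight-junction claudin family (X chromosome, 106900164 to 106930861), went from 12727 ± 1265 to 43.6 ± 4.39 units (n = 3 per group; log2 change -8.16, SE 0.089; limma adjusted p = 4.89e-14). CPLX2, which encodes the synaptic vesicle protein complexin 2 (chromosome 5, 175796310 to 175884020), went from 32755 ± 868 to 204 ± 10.5 units, a 160-fold fall. KRT4, a keratin gene, fell 145-fold, and SULT2B1, a steroid sulfotransferase gene, fell 101-fold, or 54.9 and 43.7-fold with a pseudocount of 8. Fibrinogen beta chain (FGB) fell 108-fold and coagulation factor XIII B (F13B) 53.2-fold, the latter 26-fold with a pseudocount of 8. GPX2, a glutathione peroxidase gene, went from 16862 ± 1060 to 222 ± 18.7 units, a 75.6-fold fall. KCNJ16, TM4SF4 and GALNTL6, an inward-rectifier potassium channel gene, a tetraspanin-like gene and a gene of the GalNAc-transferase family, fell 80.6, 74.6 and 53.8-fold, the last 18.3-fold with a pseudocount of 8.

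Genes were grouped in 32 lists set before the data were examined, of which 31 had at least 3 tested members. With limma's camera at a preset correlation of 0.01, 5 lists were higher and 4 were lower than the other genes at an adjusted p under 0.05. With an estimated correlation 0 lists passed, with 5 at an unadjusted p under 0.05 and adjusted p between 0.052 and 0.55 for the 9. Placing FGF21 and NKX2-1, which had 0 untreated reads, at their bounds did not move the medians of their lists. The directional test fry, which does not compare a list with other genes, called 12 lists higher and 16 lower. The member counts of each list are adjusted over all tested genes. Adjusted over the list alone, they differed for Golgi stress (19 higher) and epithelial identity (8 lower), and for no other list. Members of a called list that went against its direction or did not pass, and MT-ND2, were chosen for naming after their values were seen.

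**Figure D2:**
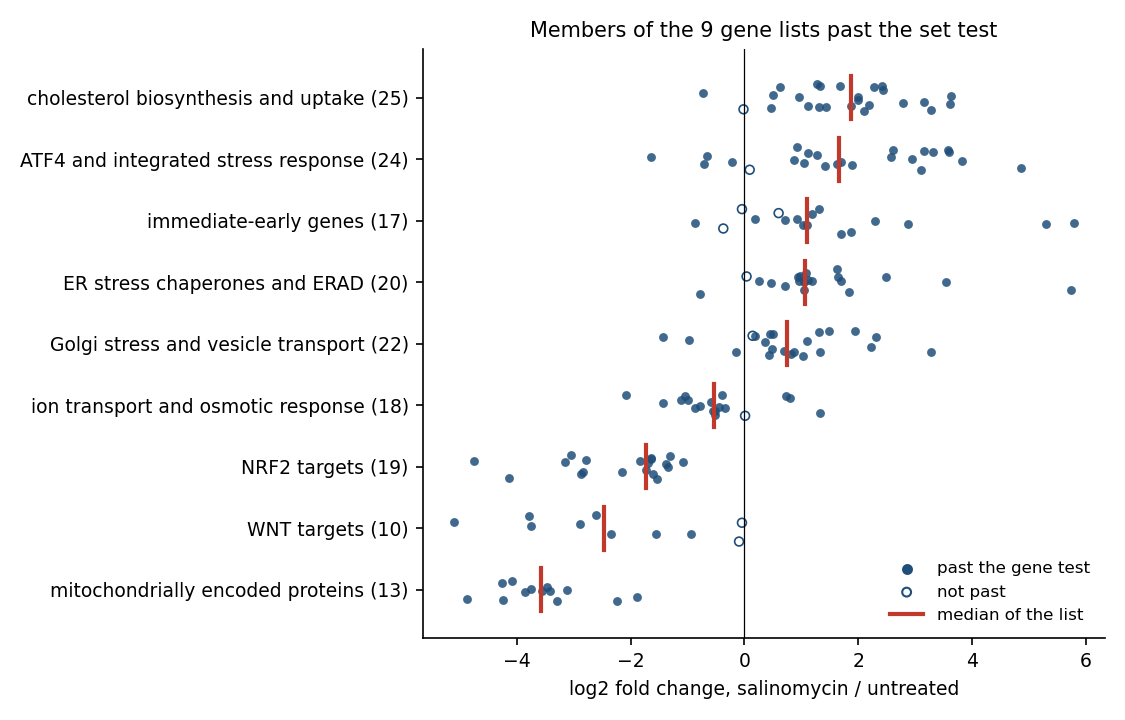
Members of the 9 lists past the set test, 1 point per tested gene on a horizontal axis of log2 fold change, salinomycin over untreated, with the number of tested members in brackets, filled points past the gene test and a red bar at the median. The medians run from -3.57 for the mitochondrially encoded proteins to 1.88 for cholesterol biosynthesis and uptake.

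Of 20 tested ER stress chaperone and ER-associated degradation genes, 18 rose and 1 fell, with a median log2 change of 1.07 (camera adjusted p = 2.5e-05; adjusted p = 0.29 with an estimated correlation). HSPA5 (chromosome 9, 125234853 to 125241330) rose most in absolute units. HERPUD1, a gene of the ER degradation machinery, rose 5.6-fold from 1273 ± 44.4 to 7138 ± 144 units, and DERL3, of the same machinery, rose 53.3-fold from 5 reads over the untreated libraries (15.7-fold with a pseudocount of 8). PDIA6, a protein disulfide isomerase gene, fell by 0.78 on the log2 scale. PDIA4, of the same enzyme class, did not pass, at 4078 and 4184 units.

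In the list of ATF4 and the integrated stress response, 19 of 24 genes rose and 4 fell, with a median of 1.66 (camera adjusted p = 4.3e-05; adjusted p = 0.2 with an estimated correlation). DDIT3, which encodes the stress-induced transcription factor CHOP (chromosome 12, 57516588 to 57521737), went from 256 ± 24.0 to 3045 ± 123 units (n = 3 per group; log2 change 3.57, SE 0.072; limma adjusted p = 2.17e-12). The secreted glycoprotein gene STC2 rose 14.2-fold and the transcription factor gene ATF3 rose 12.0-fold. FGF21, a hormone gene, had 0 untreated reads and was at least 24.7-fold higher. The 4 that fell were the cystine and amino acid transporter genes SLC7A11 (-1.64), SLC3A2 (-0.71) and SLC7A5 (-0.66), and the transcription factor gene CEBPB (-0.22).

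Cholesterol biosynthesis and uptake had 23 of 25 genes higher and 1 lower, with a median of 1.88 (camera adjusted p = 2e-07; adjusted p = 0.052 with an estimated correlation). INSIG1, which encodes an ER protein that retains the sterol sensor complex, rose 12.3-fold from 257 ± 21.2 to 3169 ± 88.1 units. Mevalonate kinase (MVK) rose 12.2-fold, and DHCR7, whose product carries out a final step of cholesterol synthesis, rose 9.7-fold from 955 ± 29.7 to 9270 ± 316 units. HMGCS1, the HMG-CoA synthase gene (chromosome 5, 43289395 to 43313512), rose 3.68-fold from 1274 ± 48.9 to 4692 ± 83.1 units (limma adjusted p = 1.37e-11). The gene that fell was the sterol reductase TM7SF2 (-0.72), and SREBF2, which encodes a transcription factor of the pathway, did not pass (2683 and 2647 units). In fatty acid synthesis 9 of 12 genes rose and 3 fell, with a median of 1.4, and the list did not pass (camera adjusted p = 0.057). The desaturase genes FADS1 and SCD rose 6.26 and 5.37-fold, and fatty acid synthase (FASN) rose 4.15-fold.

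Golgi stress and vesicle transport genes rose in 18 of 22 cases and fell in 3, with a median of 0.75 (camera adjusted p = 0.00046; adjusted p = 0.13 with an estimated correlation). The small GTPase gene ARF4 rose 9.67-fold from 2386 ± 93.2 to 23076 ± 246 units. CREB3, a membrane-bound transcription factor gene, rose 4.99-fold, and KDELR3, an ER retention receptor gene, rose 4.69-fold. CREB3L2 (-1.43), STX3 (-0.97) and GORASP1 (-0.15) fell. Among immediate-early genes 13 of 17 rose and 1 fell, or 12 and 2 with upper-quartile scaling, with a median of 1.1 (camera adjusted p = 0.0049; adjusted p = 0.55 with an estimated correlation). FOSB rose 55.2-fold and EGR1 7.31-fold, both transcription factor genes. EGR3 had 2 untreated and 219 salinomycin reads, a ratio of 82.1 after scaling for depth and library factors (95% counting interval 22.4 to 682). IER5 fell (-0.87).

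All 13 mitochondrially encoded protein genes fell, with a median of -3.57 (camera adjusted p = 1.2e-07; adjusted p = 0.41 with an estimated correlation). Their share of all values went from 3.59% ± 0.189 to 0.317% ± 0.0306 (SD, n = 3 per group; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The fall was largest for MT-CO1 (mitochondrial genome, 5904 to 7445; log2 change -4.87, SE 0.069; limma adjusted p = 2.56e-13). The other cytochrome c oxidase subunit genes MT-CO2 and MT-CO3 fell 19.1 and 18.9-fold. MT-ND2, a subunit gene of complex I, fell least, from 21738 ± 1300 to 5898 ± 582 units. Of 30 nuclear genes of oxidative phosphorylation, 15 rose, 9 fell and 6 did not pass, with a median of 0.21 (camera adjusted p = 0.27). With scaling by library size alone 20 of them rose and 5 fell, with a median of 0.4. The ATP synthase genes ATP5MC1 and ATP5F1C moved apart, by 1.33 and -0.96, and the cytochrome oxidase-associated gene NDUFA4 rose by 0.88.

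**Figure D3:**
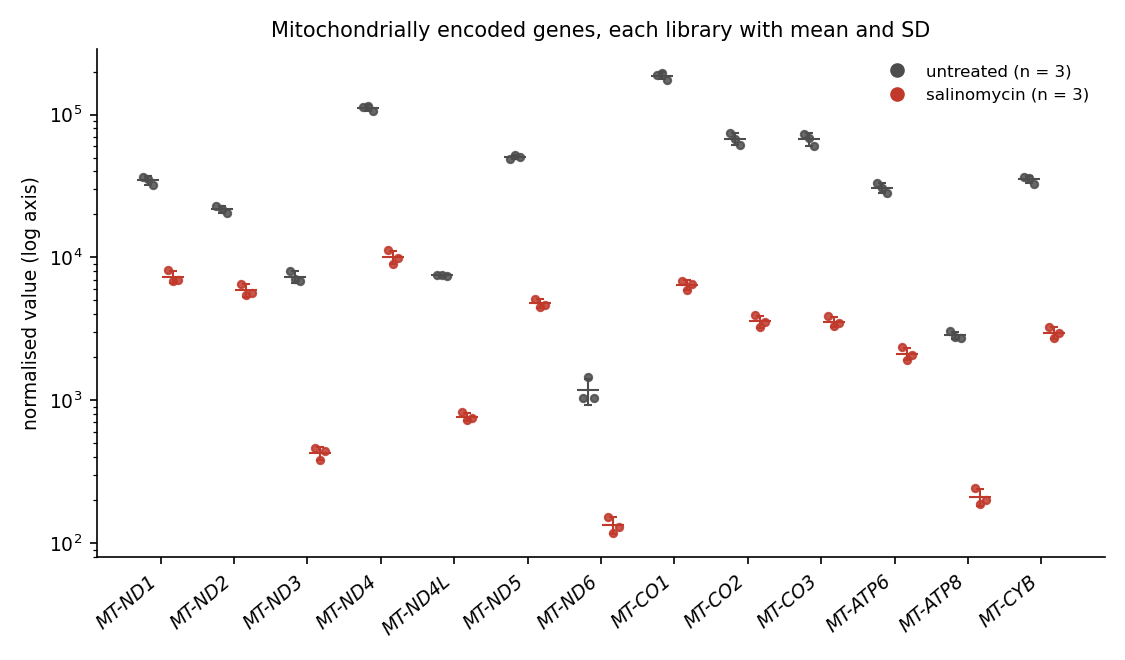
Normalised values of the 13 mitochondrially encoded protein genes on a logarithmic vertical axis, with points for the 3 untreated (grey) and 3 salinomycin (red) libraries, horizontal marks at the means and bars of 1 SD. All salinomycin values lie below all untreated values of the same gene, from a 3.69-fold fall in MT-ND2 to a 29.2-fold fall in MT-CO1.

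All 19 tested members of the list of NRF2 targets fell, with a median of -1.73 (camera adjusted p = 3e-09; adjusted p = 0.052 with an estimated correlation). The list is a selection, so NRF2 targets outside it need not have fallen. NRF2 is the transcription factor that induces antioxidant and detoxifying enzymes. ALDH3A1, an aldehyde dehydrogenase gene (chromosome 17, 19737984 to 19748943), went from 83791 ± 4757 to 3097 ± 63.8 units (log2 change -4.76, SE 0.054; limma adjusted p = 5.25e-14). The aldo-keto reductase genes AKR1B10 and AKR1C1 fell 17.6 and 8.87-fold, and both have close paralogs among which counting could have split reads. WNT targets fell in 8 of 10 tested genes, and none rose, with a median of -2.47 (camera adjusted p = 0.0024; adjusted p = 0.17 with an estimated correlation). The pathway inhibitor genes NKD1 and AXIN2 fell 34.3-fold (11.3-fold with a pseudocount of 8) and 13.4-fold, and RNF43, a ubiquitin ligase gene that limits WNT receptors, fell 13.8-fold. Under scaling by library size alone 1 WNT target rose. MYC (1289 and 1250 units) and DKK1 (2842 and 2662 units) did not pass.

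Ion transport and osmotic response genes fell in 14 of 18 cases and rose in 3, with a median of -0.54 (camera adjusted p = 0.021; adjusted p = 0.41 with an estimated correlation). SLC12A2, a sodium-potassium-chloride cotransporter gene, fell 4.21-fold, and ATP2A2, the gene of the ER calcium pump SERCA2, fell 2.68-fold. The potassium channel gene KCNK1 rose, with a log2 change of 1.32.

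Markers of senescence moved in different directions. CDKN1A, which encodes the cell cycle inhibitor p21, rose 1.35-fold from 19077 ± 939 to 25741 ± 1112 units (limma adjusted p = 1.94e-05). LMNB1, which encodes lamin B1, rose 1.71-fold. GLB1, the gene of lysosomal beta-galactosidase, fell from 3583 ± 116 to 2375 ± 70.0 units. The proliferation marker MKI67 fell 3.92-fold from 51.3 ± 18.5 units, and AURKA, the target of alisertib, rose 1.94-fold. Of 25 tested senescence-associated secreted factors, 12 rose, 11 fell and 2 did not pass, against 11 and 11 with upper-quartile scaling (camera adjusted p = 0.86, direction down, against a median of 0.19). CXCL8 rose 2.6-fold, GDF15 2.2-fold and ICAM1 7.92-fold, whereas IGFBP4 fell 9.76-fold from 87853 ± 5133 units. CCL20 had 1 untreated and 32 salinomycin reads, a ratio of 24.0 after scaling for depth and library factors (95% counting interval 4.01 to 976). IL6, with 4 and 17 reads, was below the filter and was not tested.

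**Figure D4:**
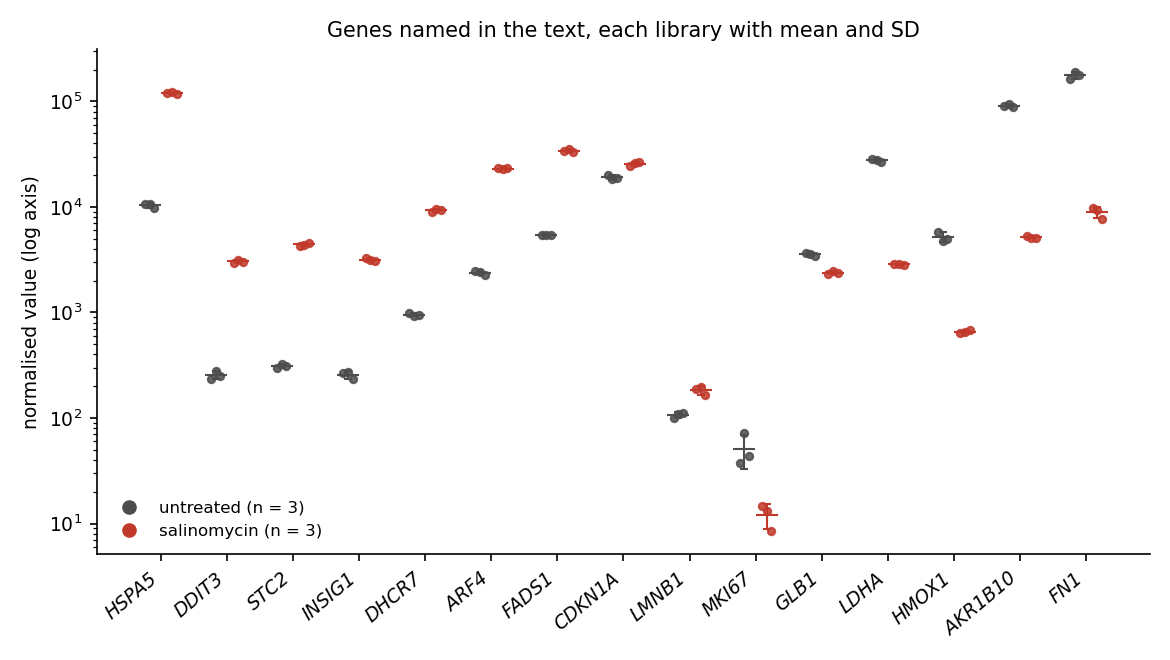
Normalised values of 15 named genes on a logarithmic vertical axis, with points for the 3 untreated (grey) and 3 salinomycin (red) libraries, horizontal marks at the means and bars of 1 SD. HSPA5 stands at 10342 and 120610 units on average, and FN1 at 176090 and 8937.

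Cell cycle genes were mixed, with 8 of 22 mitosis genes higher and 11 lower (camera adjusted p = 0.6) and 10 of 22 DNA replication genes higher and 8 lower, or 8 and 8 with upper-quartile scaling (camera adjusted p = 0.65). TOP2A and CENPF fell 7.85 and 8.32-fold, whereas the spindle checkpoint kinase gene TTK rose 6.59-fold. The replication licensing genes CDT1 and MCM6 rose 4.54 and 3.09-fold and GINS2 fell 3.66-fold. Among p53 targets 6 of 24 rose and 13 fell, with a median of -0.39 (camera adjusted p = 0.18), and TP53I3, TP53INP1 and TIGAR fell 2.92, 2.73 and 2.19-fold. Death receptors and apoptosis regulators rose in 14 of 25 cases and fell in 8, with a median of 0.56 (camera adjusted p = 0.27). TNFRSF10B, which encodes death receptor 5 (chromosome 8, 23020133 to 23069179), rose 1.66-fold from 6308 ± 107 to 10440 ± 57.1 units (limma adjusted p = 1.55e-08). The BH3-only gene HRK rose 15.5-fold (9.38-fold with a pseudocount of 8), and 2 further genes of that class, BID and BCL2L11, fell 4.18 and 3.77-fold.

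In the pyroptosis list 3 of 10 genes rose and 7 fell (camera adjusted p = 0.22). The inflammasome sensor gene NLRP1 rose 27.3-fold, and CASP1 fell 6.63-fold (4.29-fold with a pseudocount of 8). GSDMC had 137 untreated and 3 salinomycin reads. Scaled for depth and library factors, its untreated level was 60.9 times the salinomycin level (95% counting interval 20.4 to 299). Ferroptosis and iron genes rose in 6 and fell in 9 of 18 cases, or in 8 and 8 with scaling by library size alone (camera adjusted p = 0.23). The lysophospholipid acyltransferase gene LPCAT3 fell 8.53-fold, HMOX1, the gene of heme oxygenase 1, fell 7.89-fold, and SLC40A1, the gene of the iron exporter, fell 5.76-fold. Of 26 lysosome genes 5 rose and 15 fell, or 9 and 12 with scaling by library size alone (median -0.33, or -0.13 with that scaling; camera adjusted p = 0.15), with NEU1 and NPC1 up 4.12 and 2.85-fold and CTSB down 2.29-fold. Autophagy genes rose in 10 and fell in 5 of 20 cases, or in 13 and 3 with scaling by library size alone (camera adjusted p = 0.19), and MAP1LC3B, SQSTM1 and WIPI1 rose 3.3, 2.2 and 2.21-fold.

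Of 19 glycolysis genes 5 rose and 12 fell (median -0.47; camera adjusted p = 0.13). HK2 and ALDOC, an aldolase gene, rose 93 and 12.3-fold, while LDHA, the lactate dehydrogenase A gene, fell 9.64-fold from 27643 ± 855 to 2866 ± 34.3 units. Hypoxia response genes rose in 9 and fell in 6 of 16 cases, with a median of 0.31, a mean of -0.25 and a camera adjusted p of 0.63. LOX, a lysyl oxidase gene, rose 16.0-fold, and CA9 and EGLN3 fell by 4.17 and 2.86 on the log2 scale, CA9 by 2.34 with a pseudocount of 8. Cytosolic heat shock genes rose in 2 and fell in 8 of 15 cases, or in 6 and 8 with scaling by library size alone (camera adjusted p = 0.17), and HSPA8, HSPB1 and HSP90AA1 fell 3.51, 2.95 and 2.85-fold. Among 5 metallothionein and zinc export genes 3 rose and 1 fell (camera adjusted p = 0.47), with MT2A and MT1G up 4.86 and 1.93-fold and the zinc exporter SLC30A1 down 2.08-fold. Ribosomal protein genes fell in 18 and rose in 5 of 30 cases, or in 11 and 10 with scaling by library size alone and 21 and 3 with upper-quartile scaling (camera adjusted p = 0.13). RPL7 and RPL15 each fell 1.52-fold.

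NF-kB targets rose in 9 of 14 cases and fell in 5, or in 9 and 2 with scaling by library size alone (camera adjusted p = 0.35), with the subunit genes NFKB2 and RELB up 8.22 and 4.08-fold and TNFAIP3 up 3.08-fold. Interferon-stimulated genes fell in 13 and rose in 4 of 19 cases (median -0.71; camera adjusted p = 0.18). IFIT1 and OAS2 fell 5.76 and 4.21-fold, and ISG20 rose 5.35-fold. Epithelial and alveolar identity genes rose in 8 and fell in 7 of 16 cases, with a camera adjusted p of 0.86. Their median was -0.08, against 0.12 with scaling by library size alone, and their mean was 0.05. The keratin gene KRT8 fell 5.92-fold, the splicing regulator gene ESRP1 rose 7.3-fold from 4 untreated reads (2.43-fold with a pseudocount of 8), and NKX2-1, a lung transcription factor gene, had 0 untreated reads and was at least 13.7-fold higher. Mesenchymal transition genes rose in 4 and fell in 9 of 17 cases (median -0.43; camera adjusted p = 0.063). FN1, the fibronectin gene (chromosome 2, 215360440 to 215436172), went from 176090 ± 12520 to 8937 ± 1106 units (log2 change -4.31, SE 0.089; limma adjusted p = 2.62e-12), and TAGLN and SPARC fell 12.0 and 10.1-fold.

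Markers of cell types other than epithelium were also listed. Of 6 tested fibroblast markers 5 fell and none rose (camera adjusted p = 0.13), and the most abundant by mean of all libraries, COL1A1, went from 667 ± 128 to 416 ± 18.3 units. Of 4 tested blood markers 2 rose and 2 fell (camera adjusted p = 0.81), and CD14 went from 201 ± 16.0 to 30.2 ± 9.88 units. None of the 6 endothelial markers with a value was tested, and CDH5 stood at 8.92 ± 0.570 and 2.18 ± 1.43 units.

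In the authors' deposited table of the same comparison, 6337 genes were higher and 4249 lower at an adjusted p under 0.05. Of the genes so called in the authors' deposited table, 9555 were also called in the same direction by limma here and 0 in the opposite direction. HSPA5, MT-CO1 and CLDN2 had log2 changes of 3.74, -4.67 and -7.96 in the authors' deposited table, as ratios of group means without further library factors. The authors' deposited table of gene set enrichment held 21624 sets, of which 1083 were higher and 2774 lower at an adjusted p under 0.05. In the authors' deposited table, 7 of 50 hallmark sets were higher and 19 lower. The unfolded protein response set had a normalised enrichment score of 2.446 and the cholesterol homeostasis set 2.078 in the authors' deposited table. The authors' deposited table gave -2.649 for the epithelial-mesenchymal transition set, -2.251 for xenobiotic metabolism and -2.193 for coagulation. Of sets with NRF2 in their name, those lower at an adjusted p under 0.05 in the authors' deposited table ran from -1.932 to -2.236. A set named for NFE2L2, the gene of NRF2, stood at -2.583 in the authors' deposited table. Its name does not tell whether its genes rise or fall with NRF2 activity, so its score cannot be read as lower NRF2 activity. Further sets with NRF2 in their name did not pass there, with scores of 1.299, 0.902, 0.739 and -1.461 (adjusted p of the authors' enrichment from 0.176 to 0.92). A motif set with NRF2 in its name, which nuclear respiratory factor 2 shares, stood at 2.078 (adjusted p = 1.42e-10) in the authors' deposited table. All these sets were chosen after their values were seen, and how each was drawn up is not given in the sources used here.

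The p-values rest on 3 libraries per group, and counting intervals and floors cover counting error only. Fold changes are on a log2 scale with a pseudocount of 1, which understates the change of genes with low values.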

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

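The tests with pseudocounts of 0.5 and 8, with median-of-ratios scaling of the gene lists and without the mitochondrially encoded genes before scaling were chosen after the result was seen. Over all alternatives 5015 (upper-quartile scaling) to 6461 (library size alone) genes were higher and 4353 (library size alone) to 5720 (upper-quartile scaling) lower, against 5451 and 5266. Between 91.5% (library size alone) and 100% of the calls were kept, with 0 reversed, and the 118 tested named genes kept their call and direction in each alternative that tested them, while the fold of 22 of them moved by over 1.5 times with a pseudocount of 8, of 7 with 0.5 and of 5 with limma-voom, genes with low values in 1 group. Leaving out each library in turn gave 5204 to 5439 higher and 5146 to 5211 lower genes. Of the gene lists, 0 were higher and 0 lower with an estimated correlation, where the 9 called lists had adjusted p from 0.052 to 0.55 and 5 lists passed an unadjusted p of 0.05. With fry 12 were higher and 16 lower, a test that by construction does not compare a list with other genes. Fatty acid synthesis, at 0.057, passed with upper-quartile scaling (0.041), with no filter (0.031), and without untreated replicate 3 (0.041), salinomycin replicate 1 (0.05) or salinomycin replicate 3 (0.048). Mesenchymal transition, at 0.063, passed with library size alone (0.047), with no filter (0.046) and without untreated replicate 2 (0.031). Ribosomal proteins, at 0.13, passed without untreated replicate 3 (0.032). The cause was not tested. With the replicate number as a block (replicate block) 5325 genes were higher and 5130 lower and no list changed its call. Deviations of libraries with the same number had correlations of -0.17, -0.01 and -0.03, no library correlated best with its own number, and the numbers were not taken to pair the libraries. The planned count models (DESeq2 and edgeR) were not run, since the values are not raw counts. Depth limits genes with few reads. In simulated data with only 200 genes changed, 52% of 1.2-fold changes were recovered, a share that need not carry over to these data.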

Other observations

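The tests of other scalings, of the nuclear genes for mitochondrial RNA, of paralogs, of the tRNA synthetases and of the plasma proteins, with their 4 gene lists, were chosen only after the result was seen. Genes for plasma proteins, most of which the liver makes and secretes, fell together. Of 22 tested 20 fell, 1 rose and 1 did not pass, with a median log2 change of -3.61 (limma's camera adjusted p = 3.2e-07; adjusted p = 0.16 with an estimated correlation), and adjusted over the list alone the counts did not differ. FGA, the fibrinogen alpha chain gene, went from 7112 ± 913 to 135 ± 6.35 units (SD, n = 3 per group), and FGG, the gamma chain gene, fell 15.4-fold. The complement genes C3 and C5 fell 8.93 and 6.88-fold and the vitronectin gene VTN 9.7-fold, while SERPINA1, the gene of alpha-1 antitrypsin, rose 2.05-fold. The list was drawn up after falls of FGB and F13B had been seen, so its test is not independent evidence.

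Of 20 cytosolic aminoacyl-tRNA synthetase genes, whose products load amino acids onto tRNA, 16 rose and 3 fell, with a median of 0.85 (camera adjusted p = 0.00015; adjusted p = 0.16 with an estimated correlation). WARS1 rose 4.08-fold, and SARS1 and GARS1 each rose 2.43-fold, while QARS1 and TARS1 fell by 0.32 and 0.17 on the log2 scale. Of 16 mitochondrial synthetase genes 7 rose and 4 fell, with a median of 0 (camera adjusted p = 0.6), and CARS2 rose 2.87-fold while MARS2 fell 3.39-fold. The medians of the cytosolic and mitochondrial enzymes differed by 0.85 (permutation test over genes, two-sided p = 0.012 from 100000 permutations; genes are not independent replicates). The classes are not fully separate, since GARS1 and KARS1, counted as cytosolic, also encode the mitochondrial enzymes. The lowest median of the cytosolic enzymes over 3 other scalings was 0.76.

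The mitochondrially encoded transcripts fell by a median of 3.57 on the log2 scale, and the highest median over 3 other scalings was -3.37. These scalings moved the median of all genes by at most 0.19, so they could not have removed a fall of this size. The values argue only against the choice among these scalings as the whole cause. The 68 nuclear genes nearest in length, GC content and untreated level had a median of -0.15 (quartiles -0.85 and 0.12), with 3 below -3, which argues against a bias with length and GC content. That matching was partial, with median lengths of 1208.5 against 784 bases, GC of 49.3% against 44.3% and untreated levels of 8420 against 34700 units. The 22 nuclear genes for mitochondrial transcription and RNA stability had a median of 0.3, with 12 higher and 3 lower (camera adjusted p = 0.093). That argues against a joint fall of their transcripts. POLRMT rose by 1.18 and TFAM fell by 0.64, while SUPV3L1 rose most, by 1.4, and TWNK fell most, by 0.75. The list mixes genes of transcription, RNA processing, RNA decay and DNA replication, so its median decides nothing on each of these steps alone. The log2 changes of the 13 genes were unequal, from -4.87 (MT-CO1) to -1.88 (MT-ND2), with SE of at most 0.134. The log2 ratio of these 2 genes, picked as the extremes, went from 3.11 ± 0.07 to 0.12 ± 0.06 (SD, n = 3 per group). These values argue against an equal loss over all 13 genes as the whole cause. Lower mitochondrial DNA content alone would be such a loss only if it lowered each transcript in proportion, which was not tested. Faster decay, or lower mitochondrial DNA content or less transcription as a part of the fall, are hypotheses that these values leave open. They also leave open a difference in RNA capture not tied to length or GC.

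The 19 tested NRF2 targets of the list fell by a median of 1.73 on the log2 scale, and the highest median over 3 other scalings was -1.54. The 14 members outside the aldo-keto reductase families had a median of -1.64, which argues against reads shared between those paralogs as the whole cause. NFE2L2, the gene of NRF2, fell by 0.35 on the log2 scale (limma adjusted p = 2.95e-05), less than any tested target of the list, which argues against its transcript level as the whole cause. KEAP1, which encodes the protein that targets NRF2 for degradation, rose by 0.57. Whether that protein is functional in these cells was not measured, so the rise does not show more degradation of NRF2. MAFG, a partner gene outside the list of targets, rose by 0.52. BACH1, a repressor gene, was at 493 and 462 units without passing (limma adjusted p = 0.296). SQSTM1, also outside the list, rose by 1.14. A lower amount or activity of the NRF2 protein with salinomycin may be a hypothesis for the fall of the listed targets. It was not tested, since these transcripts do not measure the protein.

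For the plasma proteins, setting aside 6 members whose strong falls had been seen left 16 with a median of -3.24, 14 lower and 1 higher. As the list was drawn up after such falls had been seen, this decides nothing on whether the choice of genes made the pattern, and no biological explanation was tested.

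The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 10717 genes, and the highest of the others called 0, so that 1 split of the 10 gave as many.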
